A study of Homo sapiens with 6 samples.

How the data were processed

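H3K4me3, the trimethylation of lysine 4 of histone H3 found at promoters of active genes, was measured by chromatin immunoprecipitation and paired-end sequencing (ChIP-seq) in PC-3 cells. The 6 samples are 3 H3K4me3 libraries and 3 input libraries, 1 of each kind for untreated cells, for cells given TGF-β1 for 6 h and for cells given it for 24 h. Only the H3K4me3 libraries have peak lists here; the inputs enter only as far as the authors' peak caller used them. Groups were taken from the sample titles.

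Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic, BWA and MACS2 2.1.1.20160309, and the builds hg19 and GRCh37. Versions of Trimmomatic and BWA, caller settings, read filters and total read numbers were not given in the sources used here. The authors called peaks per library, as there is 1 deposited list per H3K4me3 library. Each deposited list gives a peak's position, its summit and 4 values of the authors. The first is a score. The others are a fold enrichment, the −log10 of the p-value and the −log10 of the q-value, both taken by the authors at the summit against the local background. The deposited score equals the whole part of 10 times the −log10 q-value for 100% of control peaks, 100% of 6 h peaks and 99.985% of 24 h peaks. The lowest −log10 q-values were 1.3011, 1.30349 and 1.31287 in the control, 6 h and 24 h lists, that is, a q-value limit of 0.05. These values belong to each peak within its own list and were used only to describe, rank or filter peaks of that list. Coordinates are printed 1-based on hg19.

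The summit pileup, the number of fragments over the summit, and the local background, the number the caller assumed there, were recovered from the authors' fold and p-value. MACS2 computes the fold as (pileup + 1) / (background + 1) and p as a Poisson tail. Both equations were solved per peak, and the pileup was rounded to a whole number. The rounded pileup gave back the deposited −log10 p within 0.01 for 99.99% of peaks in each list. The recovery was tested on simulated peaks drawn for each list (26918, 71174 and 73630 peaks) and returned 100% of the pileups. The lowest background of a list is that of the whole library and was used as the measure of depth. MACS2 by default scales the larger of ChIP and input down to the smaller, and a whole pileup is that of an unscaled ChIP library. Heights were compared between lists as multiples of this lowest background.

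The main analysis used chromosomes 1 to 22 and X. Peaks of different lists were called overlapping when they shared at least 1 bp. Overlapping peaks of the 3 lists were merged into regions, and each region was classed by the lists that hold a peak there. A region "gained" at a time has a peak in that list and none in the control list, and a region "lost" has a peak in the control list alone. These words describe lists, since a peak missing from a list is not shown to be absent from the cells. Shares carry Wilson 95% binomial intervals. These intervals take peaks or regions as independent trials, cover counting error over them only and leave out error in the calls. PCR reads are not independent molecules, so intervals of pileup ratios also cover counting error only. With 1 library per condition there is no replicate check, no test between conditions and no p-value across peaks or regions.

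Both treated lists were compared with the same control list. Their shared gain is therefore given beside the number for independent lists over 1 kb bins. It is also given beside 100 simulations in which all regions share a common control-to-treated ratio. In the simulations the mean treated height of a region in excess of the lowest background was multiplied by a control-to-treated ratio, and the background was added back. This ratio was the median at the strongest quintile of the shared regions, also of heights in excess of background. A control peak was called where a Poisson draw reached a pileup of 11. That is the pileup needed at a local background of 3.67, the median at the weakest control peaks, whereas heights were scaled by the lowest control background of 2.42. Added after seeing the data was a local background of 9.17, the control median at the strongest quintile of shared regions, at which a pileup of 20 is needed. The 1 control library cannot be divided, so part of the shared gain may come from the shared control.

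The plan fixed before the data were examined named genes with a promoter peak, with lists of TGF-β, epithelial, mesenchymal and other genes. The gene table at hand is on another assembly than the peak lists, so genes, promoter windows, positions relative to genes and gene lists were not analysed here. The plan's rule for that case was applied to regions by coordinates. It names the 10 regions gained at both times, 5 gained at 6 h only, 5 gained at 24 h only and 5 lost with the highest mean within-list percentile of significance, and the 5 widest peaks of each list. Alternatives were a q-value limit of 1e-05, a fold of at least 5, the same number of peaks in each list, merging of peaks under 1 kb apart, every sequence, an overlap of at least 50% of both peaks and a width of 3 kb in place of 5 kb for broad peaks. Added after seeing the data were leaving out peaks whose local background exceeds 5 times the lowest of their list, asking for no control peak within 1 kb, merging before classing regions, and a pileup of at least 100 when heights at 6 h and 24 h were compared. The comparison of recovered heights itself was also added then. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and overlaps were checked against bedtools 2.31.1.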

Results

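The study asked where in the genome H3K4me3 lies in PC-3 cells after TGF-β1, a cytokine that can drive epithelial cells into a mesenchymal state. PC-3 is a human prostate adenocarcinoma line derived from a bone metastasis. Cells were deprived of serum for 24 h and then left untreated or given 5 ng/mL TGF-β1 for 6 h or 24 h. Each condition had 1 H3K4me3 library and 1 input library. The recovered background pileup, used here as the depth, was 2.42 fragments in the control list, 5.34 in the 6 h list and 5.31 in the 24 h list, so the treated lists had 2.21 and 2.19 times the control depth by this measure. The shortest peak was 219 bp in the control list and 149 bp in both treated lists. If these are the fragment lengths the caller used, the ratios in fragments are 3.24 and 3.22.

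The treated lists held more H3K4me3 peaks than the control list. There were 26887 peaks in control cells, 71162 at 6 h and 73589 at 24 h, that is, 2.65 and 2.74 times the control number. Peaks covered 39.0 Mb in control cells, 94.5 Mb at 6 h and 95.6 Mb at 24 h. The added peaks were narrow, and median peak width was 982 bp in the control list against 668 bp and 659 bp in the treated lists. The typical listed summit stood lower over the lowest background of its list in the treated lists. The median pileup was 16.5 times that background in the control list, 5.62 times at 6 h and 5.84 times at 24 h. The median local background was 2.49 times the lowest in the control list against 1 in both treated lists, so summits differed less over their local background. The median fold enrichment given by the authors was 5.55, 4.26 and 4.25. The upper end stood higher, and the 90th percentile of summit pileup was 40.5 times the lowest background in the control list, 77.2 times at 6 h and 76.7 times at 24 h. The largest fold enrichment given by the authors was 27.2 in the control list, 132 at 6 h and 142 at 24 h. The ratio of peak numbers has no replicate check, and depth and treatment differ between the same libraries.

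The 5 strongest peaks by significance of both treated lists lay at the same places. On chromosome 14, the peak at 73357206–73362885 led the 6 h list by q-value and had a pileup of 2200. The peak at 73356932–73362805 led the 24 h list by q-value and had a pileup of 2206. Peaks at chr14:73602449–73606176, chr14:73523929–73529349, chr12:73574–75953 and chr14:90862112–90867078 followed at 6 h, each with a partner among the 5 strongest at 24 h. Their local background was 3.98 to 5.43 times the lowest of the 6 h list. The 10 most significant control peaks were of another kind, with a local background of 237 to 4574 times the lowest. They included chr1:121485066–121485381, chr10:42596899–42597177, chr18:18518856–18520326 and chr7:61970255–61970540, with folds of 1.98 to 4.29. These named strongest peaks fall outside the naming rule and were chosen after their values were seen.

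The first comparison asked which H3K4me3 places of untreated cells were still listed after TGF-β1. Nearly every control peak had a treated partner. Of the control peaks, 97.3% (95% interval 97.1 to 97.5) overlapped a 6 h peak and 97.7% (97.5 to 97.9) a 24 h peak. In the other direction, 31.5% (31.2 to 31.8) of 6 h peaks and 30.7% (30.4 to 31.0) of 24 h peaks overlapped a control peak. With the 26887 most significant peaks taken from each list, those shares were 75.9% and 76.1%, and 89.9% and 90.0% of control peaks had a 6 h and a 24 h partner.

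Treated peaks without a control partner were the weaker ones of their own list. In the weakest decile of the 6 h list, 98.9% of peaks had no control peak. The peaks of this decile had a median width of 214 bp, below the shortest control peak of 219 bp. A different minimum width may therefore add to this share, which was not measured. The share was 75.2% in the seventh decile, 33.0% in the eighth and 1.18% in the ninth. In the strongest decile, 2 of 7116 peaks at 6 h and 2 of 7358 at 24 h had none. At 24 h the seventh, the eighth and the ninth decile gave 76.8%, 37.6% and 1.69%.

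**Figure D1:**
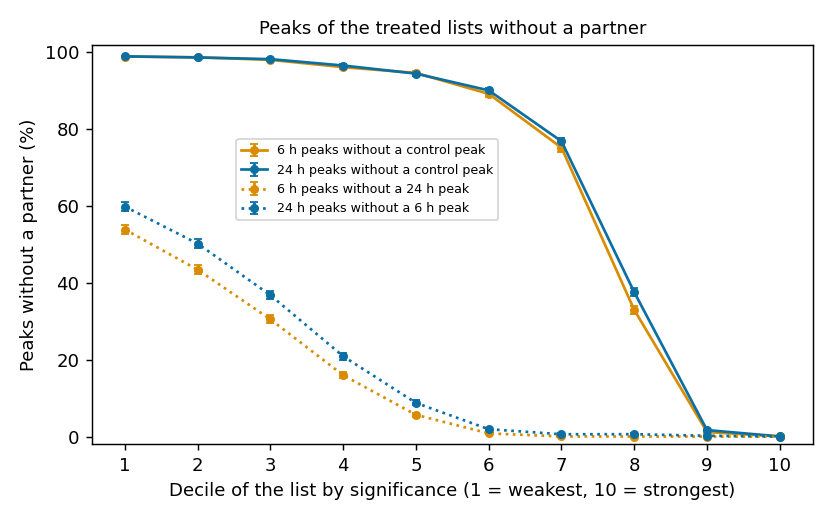
Share of treated peaks without an overlapping peak in another list (y axis, percent) in each decile of the list by significance (x axis, weakest to strongest), with Wilson 95% intervals. Solid lines count peaks without a control peak and dotted lines peaks without a peak at the other time; the solid lines fall from 98.9% in the weakest 6 h decile to 1.18% in the ninth.

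Merging the lists gave 81484 regions. All 3 lists held 22189 of them, with a median width of 2601 bp and 69.0 Mb in sum. Regions gained at both times numbered 34895, were narrower (median 696 bp) and summed to 30.0 Mb. A further 10611 regions were gained at 6 h only and 13026 at 24 h only, with median widths of 252 bp and 263 bp. In 491 regions the control list alone held a peak. The control list shared 78 regions with the 6 h list alone and 194 with the 24 h list alone.

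**Figure D2:**
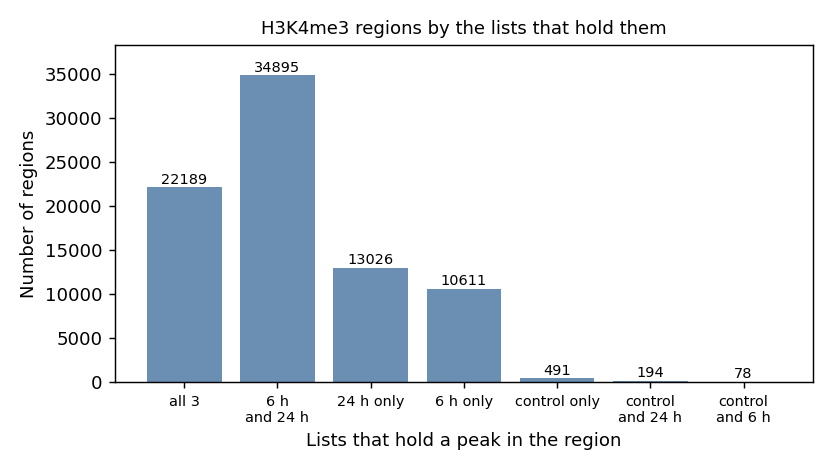
Number of H3K4me3 regions (y axis) by the lists that hold a peak there (x axis), 1 library per condition. Regions of both treated lists without a control peak (34895) outnumber those in all 3 lists (22189), and 491 regions are in the control list alone.

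Regions gained at both times had a median summit pileup of 26 at 6 h and 27 at 24 h, against 278 and 277 in the regions of all 3 lists. Of the gained regions, 29.1% were at least 1 kb wide, 307 were at least 3 kb and 35 at least 5 kb. A control peak lay within 5 kb of 17.0% (16.6 to 17.4) of them, and the median distance to a control peak was 26.4 kb. In 1 kb bins without a control peak, 93896 were gained at 6 h, 96937 at 24 h and 78268 at both, where independent lists would share 3065. The independent number treats every such bin as equally open to a peak, so an excess over it does not show a shared response to TGF-β1. Libraries were simulated that differed only in depth and in a common control-to-treated height ratio. That ratio came from these same lists, so a genome-wide rise of H3K4me3 would be built into it. The lists themselves did not hold to a common ratio. By quintile of 6 h pileup, weakest to strongest, the median log2 of control to 6 h height at shared regions was −0.206, −0.924, −1.35, −1.48 and −1.55. Weak regions enter only with a control peak, which raises their ratio, and the effect of this trend on the simulated number was not tested. With the treated lists held as observed, the simulations gave 33724 to 33974 gained regions, against 34895 observed. Drawing the treated lists anew, which loses some of their weak regions by construction, gave 31712 to 32006. With the control local background set to 9.17, its median at the strongest shared regions, the model gave 41464, so the number rests on that setting. What the shared control contributes to this overlap was not measured.

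Of the regions gained at both times, chr9:66696817–66697643 ranked highest, with pileups of 755 at 6 h and 706 at 24 h and a control peak 0.425 kb away. Next came chr16:30205632–30206473 with pileups of 535 and 468, and chr11:311132–312599 with 335 and 350. The nearest control peaks to these lay 10.3 kb and 0.812 kb away. The other 7 named regions were chr1:142890552–142891528, chr7:102256705–102257917, chr17:58103730–58104484, chr9:44989843–44990922, chr7:72424195–72425976, chr17:58196756–58197565 and chr10:51370573–51371375. Their pileups ran from 300 to 402 at 6 h and from 300 to 397 at 24 h. Of the 10, 8 had no control peak within 1 kb.

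The gained regions were spread differently over the chromosomes than the shared ones. Chromosome 19, a gene-dense chromosome, held 5.83% (5.53 to 6.14) of the regions of all 3 lists and 2.71% (2.55 to 2.89) of those gained at both times, a ratio of 0.465. Chromosomes 22, 16 and 17 had ratios of 0.631, 0.640 and 0.728. Chromosomes 18 and 8 had the highest ratios, 1.43 and 1.40, and chromosome 8 held 4.32% (4.06 to 4.59) of the shared and 6.03% (5.79 to 6.29) of the gained regions. The spread was not particular to gain at both times. Chromosome 8 held 6.32% of the regions of 6 h only and 5.90% of those of 24 h only, and chromosome 19 held 2.83% and 4.22%. Gained regions were weaker than shared ones, and what peak strength adds to the contrast was not tested. The 1 Mb window with the most regions gained at both times was chr8:134000001–135000000, with 56 of them and 5 regions of all 3 lists.

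**Figure D3:**
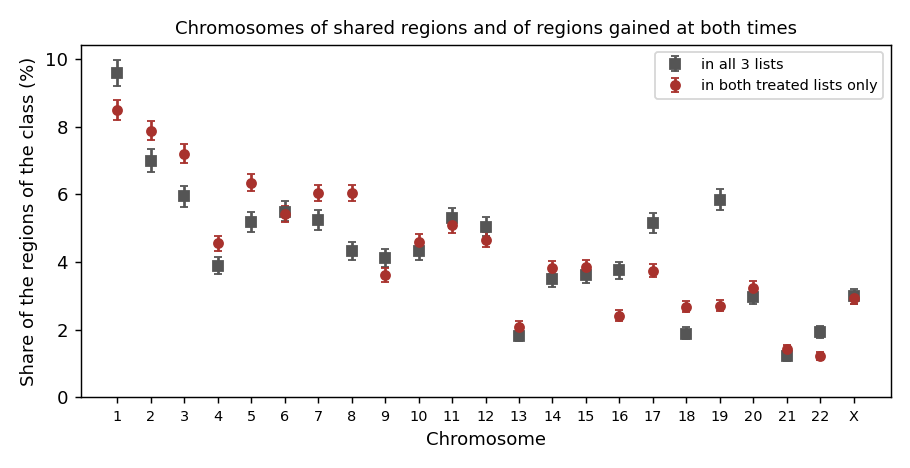
Share of regions on each chromosome (y axis, percent; x axis, chromosome) for regions in all 3 lists (squares) and regions in both treated lists only (circles), with Wilson 95% intervals for counting error. Chromosome 19 holds 5.83% of the former and 2.71% of the latter, and chromosome 8 holds 4.32% and 6.03%.

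Regions of the control list alone were few and weak, with a median pileup of 12. Of the 5 named ones, 4 had a local background over 5 times the lowest: chr2:92275840–92276069, chr4:49512159–49512420, chr4:49318842–49319060 and chr7:61079154–61079383. The exception, chr4:49309258–49309488, had a pileup of 42 and a local background of 1.52 times the lowest. With the same number of peaks in each list, the number of regions lost was 2274 against 4716 gained at both times. The treated lists were cut by rank for this and the control list was not. In the full lists 612 control peaks had no 24 h partner, so most of the 2274 regions overlap a treated peak that was cut. With a q-value limit of 1e-05, the numbers were 93 and 23921.

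Within the regions of all 3 lists, called peaks covered more of the region in the treated lists. Covered length depends on depth and local background, and both differed between the lists. The median covered length was 1390 bp in the control list, 2497 bp at 6 h and 2478 bp at 24 h. Treated peaks covered more bases than control peaks in 99.1% of these regions at 6 h and in 99.3% at 24 h. The control list split 14.0% of them into several peaks, against 5.47% at 6 h and 6.06% at 24 h.

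Broad H3K4me3 peaks, those of at least 5 kb, were more numerous in the treated lists. There were 532 in the control list, 2950 at 6 h and 2885 at 24 h, that is, 5.55 and 5.42 times the control number. Of the broad 6 h peaks, 2936 (99.5%) overlapped a control peak, and in 1366 (46.3%) that control signal was split into several peaks. All 524 regions broad in the control list were broad at both times, and 2090 more were broad at both times and not in the control list. The ratios depended on the width chosen, and for peaks of at least 3 kb they were 2.69 and 2.66. The width of a peak depends on depth and on the caller's settings.

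The widest region was chr7:27198895–27248012. It was a single peak of 49.1 kb at 6 h and of 49.0 kb at 24 h, and 3 control peaks covered 46.6 kb of it. Its summit pileups, not scaled for the different depth of the lists, were 515 at 6 h and 499 at 24 h, and 71 to 72 in the control peaks. In chr22:46459086–46485960 the treated peaks were 26.9 kb and 26.6 kb wide and the widest control peak 23.6 kb. Control signal covered less of the other wide regions. In chr1:94689889–94715144, 4 control peaks covered 14.9 kb where the 6 h peak had 25.2 kb, and in chr1:16463292–16487314, 8 control peaks covered 13.0 kb of a 6 h peak of 24.0 kb. In chr3:98602474–98626061 the control peaks covered 10.2 kb against 23.4 kb at 6 h. In chr11:118777439–118801718 they covered 18.5 kb against 23.9 kb at 24 h, and in chrX:45606465–45636814 12.1 kb against 29.5 kb. The widest control peaks also included chr14:38054554–38069603 with 15.1 kb and chr7:41733252–41746671 with 13.4 kb.

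**Figure D4:**
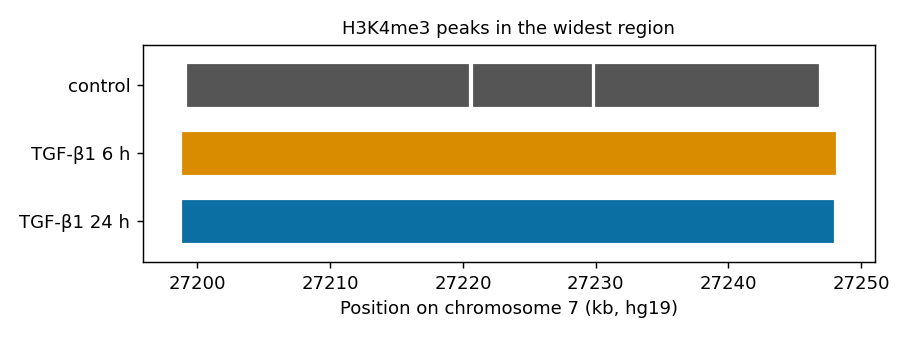
Peaks of the 3 lists (rows) along the widest region on chromosome 7 (x axis, kb on hg19), each bar being 1 peak drawn to scale. Control signal falls into 3 peaks of 21.1, 8.81 and 16.7 kb, and each treated list has 1 peak of 49.1 or 49.0 kb.

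The second comparison asked how 6 h and 24 h of TGF-β1 differ. The treated lists shared most of their peaks. Of the 6 h peaks 85.0% (84.7 to 85.2) overlapped a 24 h peak, and of the 24 h peaks 82.0% (81.7 to 82.3) overlapped a 6 h peak. Peaks without a partner were weak. In the weakest decile 53.9% of 6 h peaks and 59.8% of 24 h peaks had none, and in the strongest decile 0 of 7116 and 0 of 7358 had none, which allows shares of up to 0.0540% and 0.0522% (Wilson).

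Regions gained at 1 time only were narrow and low, with a median pileup of 17 at either time. Among the 5 named regions of 6 h only, chr3:185266593–185267094 had a pileup of 41, chr11:130731678–130731989 had 38, chr5:37495029–37495616 had 44 and chr7:26745479–26745894 had 37. The remaining 6 h region, on chromosome 11, had a local background 8.10 times the lowest. All 5 named regions of 24 h only had a local background at least 80.8 times the lowest, with folds of 1.15 to 2.89. They were chr10:79270111–79270346, chr14:65895191–65895356, chr5:148489649–148489821, chr14:71526971–71527121 and chr19:27732590–27732854. The first 3 carried the same deposited fold, 1.33, and the same −log10 q-value, 545.784. Without peaks of high local background, a choice made after seeing the data, chr17:22245503–22246017 ranked highest at 24 h only, with a pileup of 121, followed by chr2:90381295–90381715 with 141. More regions were gained at 24 h only than at 6 h only, but with the same number of peaks in each list the order turned, with 1524 at 24 h only and 1603 at 6 h only.

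Chromosome 19 held 4.22% (3.89 to 4.58) of the regions gained at 24 h only and 2.83% (2.53 to 3.16) of those gained at 6 h only. The 5 windows of 1 Mb with the most 24 h-only regions were on this chromosome, starting at 53000001, 52000001, 12000001, 58000001 and 9000001. They held 56, 53, 49, 47 and 32 such regions, against 20, 26, 18, 17 and 16 regions of 6 h only. The difference depended on the limits set. Trimmed lists were classed anew, so a region counts as 24 h only also where its 6 h peak was cut. The trimmed shares therefore cover partly other regions and cannot show what the difference in the full lists rested on. With a q-value limit of 1e-05 the chromosome 19 shares were 2.46% (2.13 to 2.84) at 24 h only and 2.42% (2.01 to 2.92) at 6 h only, and with a fold of at least 5 they were 2.28% and 2.77%. With the same number of peaks in each list the order turned, with 2.1% (1.49 to 2.95) at 24 h only and 3.49% (2.70 to 4.51) at 6 h only. With peaks under 1 kb apart merged they were 3.17% and 2.49%.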

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

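Some tests in this part were chosen after the result was seen: the control-to-treated height set against a genome-wide rise, the count of strong gained regions against the simulations, the model at a higher control local background, the chromosome 19 tests of local background and of a uniform excess at 24 h, and the distance to high background without peaks in the region itself. The background test was planned on medians, which a floor in the local background fixes near 0, and was replaced by means. The test of a uniform excess is the third tried, after earlier forms that rested on how the windows were picked and pointed the same way.

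The recovered local background, which comes from the inputs as far as the caller used them and was not part of the comparisons, stood out in the control list. At control summits in regions of all 3 lists it was 2.57 times the lowest background of the list, against 1.09 at 6 h and 1.05 at 24 h. From the weakest to the strongest quintile of these regions by 6 h pileup, it went from 1.74 to 3.79 in the control list. The treated lists went from 1 to 1.53 at 6 h and from 1 to 1.51 at 24 h. A higher local background lowers the fold and significance of a peak, and its part in the smaller number of control peaks was not tested. In the control list 236 peaks had a local background above 10 times the lowest, against 100 at 6 h and 193 at 24 h.

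The treated lists held more peaks than the control list. Splitting by the caller is argued against, since the 6 h list still had 2.43 times the control number after peaks under 1 kb apart were merged. A shallower, more weakly enriched control library remains open and would go with several values: 76.1% of the 6 h peaks outside the strongest decile lacked a control peak against 0.0281% inside it, the lowest control background was 0.453 of that at 6 h, although 6.28% of control peaks lie at that lowest value, and a model of depth and enrichment put the share of treated regions held by the control list 1.83 percentage points above the observed 38.9%. That model rests on its settings: it gave 0.693%, 3.04% and 81.9% in the first, the second and the fourth quintile by height where 2.0%, 6.0% and 69.6% were observed, and 33851 gained regions, or 41464 at a higher control local background, against 34895 observed. The share without a control peak outside the strongest decile was bound to be high, since 31.5% of all 6 h peaks overlapped a control peak. A genome-wide rise of H3K4me3 after TGF-β1 and weaker enrichment of the control library cannot be told apart, because control summits reached 0.338 of the treated height over background at the strongest shared regions, as either would give, and there is no second control library.

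A set of 93 regions was strong in both treated lists without a control peak, each with a modelled chance below 0.001 of being missed at a control local background of 3.67. Chance misses in a shallow control list stay open. The number of such regions, 93, exceeded the highest of 100 simulations, 2, at a control local background of 3.67. It lay within the range of 66 to 115 at 9.17, where 26 regions still had a modelled chance below 0.001 and 0.263 were expected. This goes against chance for those 26 only if their own control background, which is not known, was no higher. The model also gives every region the same control-to-treated ratio, so a spread in that ratio could add misses. A different handling of reads from repeated sequence is a candidate explanation. Of the 93 regions, 35.5% (26.5 to 45.6) lay within 1 Mb of a peak with a local background above 10 times the lowest, against 9.93% (9.55 to 10.3) of the regions of all 3 lists. The shares were 31.2% (22.7 to 41.2) and 9.76% (9.37 to 10.2) when peaks in the region itself were left out. Of the 93, 15 had a treated peak with a local background above 5 times the lowest, 24 had a control peak within 5 kb, and 60 lay farther than 1 Mb from such high background, among them chr16:30205632–30206473 and chr11:311132–312599. Repeated sequence with a lower local background would not be found by this distance, so the 60 are not cleared of that explanation. A gain of H3K4me3 after TGF-β1 stays open and untested for these regions.

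The 5 windows of chromosome 19 were picked as those densest in 24 h-only regions, and 71.0% of their regions of 1 treated list alone were of the 24 h list. With these list labels drawn at random over all such regions and the 5 densest windows picked anew, 1000 draws gave 46.1% to 63.8%, which argues against a uniform excess of weak 24 h peaks, as far as neighbouring regions are independent. A higher input background at 6 h stays open, since the mean log2 difference of 0.0192 (−0.0103 to 0.0484) between these windows and the rest covers only regions with a 6 h peak, and 51.4% of those in the windows lie at the floor. A higher pileup at 24 h cannot be told apart from none, with a median log2 difference of 0.0251 (−0.00406 to 0.0559) over 348 regions whose interval spans the bound, and of 0.113 over the 189 of these without a control peak and −0.0102 over the 159 with one. A change between 6 h and 24 h of TGF-β1 remains untested, and the excess on this chromosome was not seen at a q-value limit of 1e-05 and turned with equal numbers of peaks. Both settings class regions anew and so cover partly other regions.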

How the results depend on the processing

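Of 141 values over 28 results and 10 alternatives, 71 stayed within 1.5 times (counts) or within the interval (shares) and 70 moved. None changed sign, as none was a signed result. The treated lists held more peaks than the control list under 5 of the 6 alternatives in which peaks were counted, the exception being the one that fixes their number. A fold of at least 5 left 14389, 30679 and 31361 peaks in the control, 6 h and 24 h lists. A q-value limit of 1e-05 left 47338 peaks at 6 h, and equal numbers left 26887 per list. At 3 kb there were 3254, 8754 and 8658 broad peaks.

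Overlap shares follow in the order control in 6 h, control in 24 h, 6 h in control, 24 h in control, 6 h in 24 h and 24 h in 6 h. They were 99.1%, 99.5%, 37.5%, 35.2%, 90.7% and 85.1% with the q-value limit, 99.8%, 99.8%, 44.4%, 43.5%, 91.2% and 89.4% with the fold limit, and 89.9%, 90.0%, 75.9%, 76.1%, 92.7% and 92.9% with equal numbers. With 50% of both peaks required they were 48.7%, 49.3%, 18.4%, 18.0%, 68.8% and 66.5%. Merging gave 37.8%, 36.9%, 88.1% and 85.5% for the last 4. Leaving out high local background, chosen after seeing the data, gave 29.1% and 28.3% of 6 h and 24 h peaks in control.

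Regions gained at both times, at 6 h only, at 24 h only and lost numbered 14020, 2706, 3333 and 20 with the fold limit, and 4716, 1603, 1524 and 2274 with equal numbers. The q-value limit gave 4376 and 7482 at 6 h and 24 h only and 93 lost, and merging, for regions chosen after seeing the data, 6743 and 8429 at 6 h and 24 h only. Equal numbers fix the list lengths by construction, and most of their lost regions overlap a treated peak cut by rank. For the other moved values the cause was not tested. The alternatives on genes, promoter windows and gene types were not run, as genes were not analysed here. No paired analysis was possible because no result comes from a test and each condition has 1 library. The recovered depth differs between the lists, and what a deeper control library would add was not analysed here.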

Other observations

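The comparison of recovered summit heights between 6 h and 24 h was chosen after seeing the data. Over 25580 regions of both treated lists with a pileup of at least 50 at either time, heights over background were close at 6 h and 24 h. The median log2 ratio of 24 h to 6 h was 0.02 with an SD over regions of 0.22, and 97.3% of regions lay within 1.5-fold. A further 147 regions were left out for high local background. The Spearman correlation across regions, which are not independent replicates, was 0.981.

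Heights differed by at least 2-fold in few regions, 22 higher and 11 lower at 24 h. The region chr13:42262996–42266207 had pileups of 23 at 6 h and 62 at 24 h, a ratio over background of 2.71 (1.66 to 4.59, counting error only). At chr11:102823604–102826900 the pileups were 65 and 153, a ratio of 2.37 (1.76 to 3.22), with no control peak. At chr15:82385738–82388127 they were 50 and 113, a ratio of 2.27 (1.62 to 3.24). Lower at 24 h were chr16:1126472–1129347, with pileups of 201 and 95 and a ratio of 0.476 (0.369 to 0.610), and chr2:169925359–169928500, with 88 and 40 and a ratio of 0.457 (0.307 to 0.672). With a pileup of at least 100 at either time, 4 regions were higher and 1 lower. These regions were chosen for their size among many and have no replicate check.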
